A study of Mus musculus with 15 samples.

How the data were processed

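Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open chromatin, in pancreatic islets from 15 male mice aged 3 months. All mice carried floxed Arid1a alleles and the MIP-rtTA transgene, in which an insulin promoter drives a doxycycline-dependent activator. The βKO mice also carried TRE-Cre, so that Cre is made where the activator binds doxycycline. Per the labels' protocols, doxycycline was given at 1 g/L for 2 weeks, partial pancreatectomy (PPx, surgical removal of part of the pancreas) followed 1 week after its withdrawal, and islets were taken 6 days after PPx. Each library came from 40000 islet cells, was transposed at 37 °C for 30 min and was read as single ends of 75 bp.

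The submitters' processing notes name cutadapt, BWA, MACS, DiffBind and ChIPseeker, with the build mm10 (GRCm38). Their versions, the order of steps and the peak caller's settings are not given in the sources used here, nor is any shift of reads for the Tn5 cut. Each of the 4 deposited tables holds 1 comparison, with peaks of 601 bp. Per the file headers, the deposited tables give for each peak a mean log2 concentration, the log2 concentration of each group and a log2 fold between the groups. The deposited tables also hold a p-value and an FDR per peak, per the file headers, with the number of libraries in which the peak was called. The log2 fold in the authors' tables equals the difference of the group columns within 0.01. It was coded as control minus βKO or before minus after, and its sign was turned here so that positive values mean higher in βKO or after PPx. Normalization was the authors' own. The level of a group at the same peak could differ between comparisons, as at Arid1a exon 9 in βKO islets before PPx (5.49 and 5.26). At the Hes6 promoter, βKO islets after PPx read 4.52 in both comparisons. βKO islets before PPx also read higher in the genotype comparison than in the comparison of times at other promoters, chosen after their values were seen. These were Hspa5 (4.93 and 4.70), Id2 (4.72 and 4.49) and Mrps14 (3.88 and 3.65). The step was alike at these peaks, so the scale of this group differed between the comparisons. Levels taken from different comparisons are therefore not strictly on 1 scale. Values per library were not analysed here, so the depth of each library is unknown, no library could be left out, no other split of the libraries was counted, and the spread between mice is known only through the authors' p-values.

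Rows that repeated a peak were counted as 1 peak, and 1 empty row was dropped from the table of βKO against control before PPx. The authors' FDR was 1 at 4534 of 13111 peaks of the comparison of genotypes after PPx, whose median log2 concentration was 3.17 against 4.23 at the others. The FDR of the others was near a Benjamini-Hochberg adjustment over these peaks but not equal to it. Without the Arid1a exon 9 peak, 8576 peaks had an FDR between 0.994 and 1.03 times the adjusted value, while that of Arid1a was 3.50 times the value for its rank. Peaks with an FDR under 0.05 in the authors' tables are called opened (higher) or closed (lower). The promoter class, gene, exon and intron are those of the authors' annotation, and coordinates are 1-based positions on mm10.

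The analysis used Python with pandas, numpy and scipy. A standard error per peak was derived from the deposited fold and p-value. Where the p-value was 0.5 or more, or the log2 change was under 0.1, the median standard error of peaks of like concentration was used, in 20 bins. Peaks whose p-value of 0.5 or more stood beside a change over 2 such errors were left out of these approximate tests, a choice made after seeing the data. This left out 1 peak after PPx in the genotype comparison and 2 peaks in the control comparison of times. From these errors an approximate normal test was made of each change relative to the median of its table, and of the interaction of genotype and PPx, both with Benjamini-Hochberg adjustment. Peaks of different tables were matched when they shared at least 1 bp. The 17 gene lists were fixed before the data were examined. They were tested as planned by Fisher's exact test of opened against closed peaks, and by a permutation test added after seeing that few peaks closed. In the permutation test, each list's mean change relative to the median of its stratum was set against 10000 draws of peaks from the same 10 bins of concentration and the same promoter class. Both tests treat peaks as independent, which neighbouring and co-regulated peaks are not. For pairs of tables that share libraries, 100 simulated sets of unchanged groups gave the correlation and covariance that sharing alone produces. For the overlap of opened peaks between the comparisons that share the βKO libraries after PPx, 100 further sets held a gain alike at all peaks.

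The steps were tested on simulated data with the real tables' errors. For βKO against control after PPx, the test relative to the median called 90.7% of peaks changed by 2 and 99% of those changed by 3 on the log2 scale, with 11 calls among the unchanged peaks of 13111. For βKO after against before PPx it called 76.9% and 96.9%, with 4 false calls among 12767 peaks. The interaction test called 95% of peaks changed by 3 among 7504, with 12 false calls. The list permutation test was tried on 100 random lists of 20 peaks in the comparison of genotypes after PPx alone. It gave p under 0.05 for 3% of unchanged lists and for 100% of lists raised by 0.5. Many of the gene lists held fewer peaks, and its power for those and for the other comparisons was not tested.

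Genes named in the text followed a rule fixed before the data were examined. Per table, these were the 8 genes with the largest change in each direction at peaks past the threshold and of at least median concentration among them, without predicted genes. The rule also took up to 3 genes per list and direction by smallest FDR, the 4 genes with most peaks past the threshold (ties in alphabetical order), every Arid1a peak, and each EGF, neuregulin or ERBB list gene past the threshold. Other genes are marked as chosen after their values were seen. The alternatives tried were stricter thresholds, a minimum fold, a filter on weak peaks, autosomes alone, a stricter overlap, other promoter and list rules, and, added later, adjustment over all listed peaks, centring on the median and counting repeated rows. The 23 motif searches that were planned were not run because a genome sequence was not used here.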

Results

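Before PPx, islets of 4 control mice and of 3 mice with an induced deletion of Arid1a in β cells per the labels (βKO) were profiled. The deletion itself was not verified here. After PPx, at 6 days, both groups held 4 mice. Arid1a encodes a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex, and the design asks how its loss in β cells alters chromatin accessibility at rest and during the response to tissue loss. The 4 comparisons listed between 7826 and 13111 peaks. Of the peaks listed in the comparison of genotypes after PPx, 12043 had been called in at least 2 of the βKO libraries and 5775 in at least 2 of the control libraries, per the authors' deposited table. Before PPx the corresponding numbers were 5579 in βKO and 5632 in control libraries. The median peak had a log2 concentration between 3.78 and 4.02, which limits the precision at single peaks. The median standard error implied by the authors' p-values lay between 0.38 and 0.48 on the log2 scale.

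Before PPx, a single peak passed the threshold between βKO and control islets, and it lies within Arid1a itself. At chromosome 4, 133692981 to 133693581, in exon 9 of 20 of Arid1a, the log2 concentration was 1.21 in control and 5.49 in βKO islets in the authors' deposited table, a log2 change of 4.28 at an FDR of 0.00187. This peak was called in 0 of 4 control and 3 of 3 βKO libraries, per the authors' deposited table. The other 7825 peaks had an FDR of 1, and the median log2 change was 0.00. With 3 βKO and 4 control mice, the lack of further calls does not show that the genotypes were otherwise alike. At an unadjusted p under 0.05, the authors' deposited table held 66 higher and 180 lower peaks, where 391 would be expected by chance among 7826.

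None of the islet gene lists had a further peak past the threshold before PPx. The β cell identity list had peaks at 13 of its 30 genes. Its peak with the smallest p, chosen after its values were seen, was in intron 2 of the zinc transporter gene Slc30a8 and read 4.51 in control and 3.06 in βKO islets in the authors' deposited table, at an FDR of 1. Adjusted over the list alone, 1 of its 15 peaks passed. At Ins1, an insulin gene given here after its values were seen, the promoter peak read 4.12 in control and 5.08 in βKO islets, at an FDR of 1 in the authors' deposited table.

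Peaks near TGF-β and BMP signalling genes stood slightly above matched peaks in βKO islets before PPx. The mean excess over 13 peaks at 11 genes was 0.31 on the log2 scale, by a permutation test with p = 0.0016 and an adjusted p of 0.0256 over the lists of this comparison. Adjusted over the lists of all 4 comparisons it was 0.0594, which does not pass. None of these peaks passed the authors' FDR, and 0 passed when adjusted over the list alone. The promoter of Acvr2a, an activin receptor gene chosen after its values were seen, read 4.72 in control and 5.51 in βKO islets in the authors' deposited table. The SWI/SNF list, also without a pass over all 4 comparisons, exceeded its matched peaks by 0.50 (permutation test, p = 0.006), but the excess was 0.00 without Arid1a (permutation test, p = 0.95). The EGF, neuregulin and ERBB list and the cell cycle list gave adjusted p-values of 0.31 and 0.30 in the permutation test.

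At 6 days after PPx, accessibility was higher in βKO than in control islets at most peaks. In the authors' deposited table, 1296 peaks opened and 11 closed among 13111, and 90.3% of all peaks had a higher value in βKO islets. The median log2 change was 0.61, a 1.53-fold difference, and the changes of single genes below are as deposited unless given relative to it. Relative to that median, 2 peaks were higher and 49 lower at an adjusted p under 0.05 in the approximate test. The higher ones were the Arid1a exon 9 peak and a peak in intron 5 of 13 of Ak5, an adenylate kinase gene. The other peaks named below by the rule fixed beforehand stood between 0.21 (Pik3r2) and 0.90 (Pdcd2) above the median, and none had an approximate adjusted p below 0.613 relative to it.

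**Figure D1:**
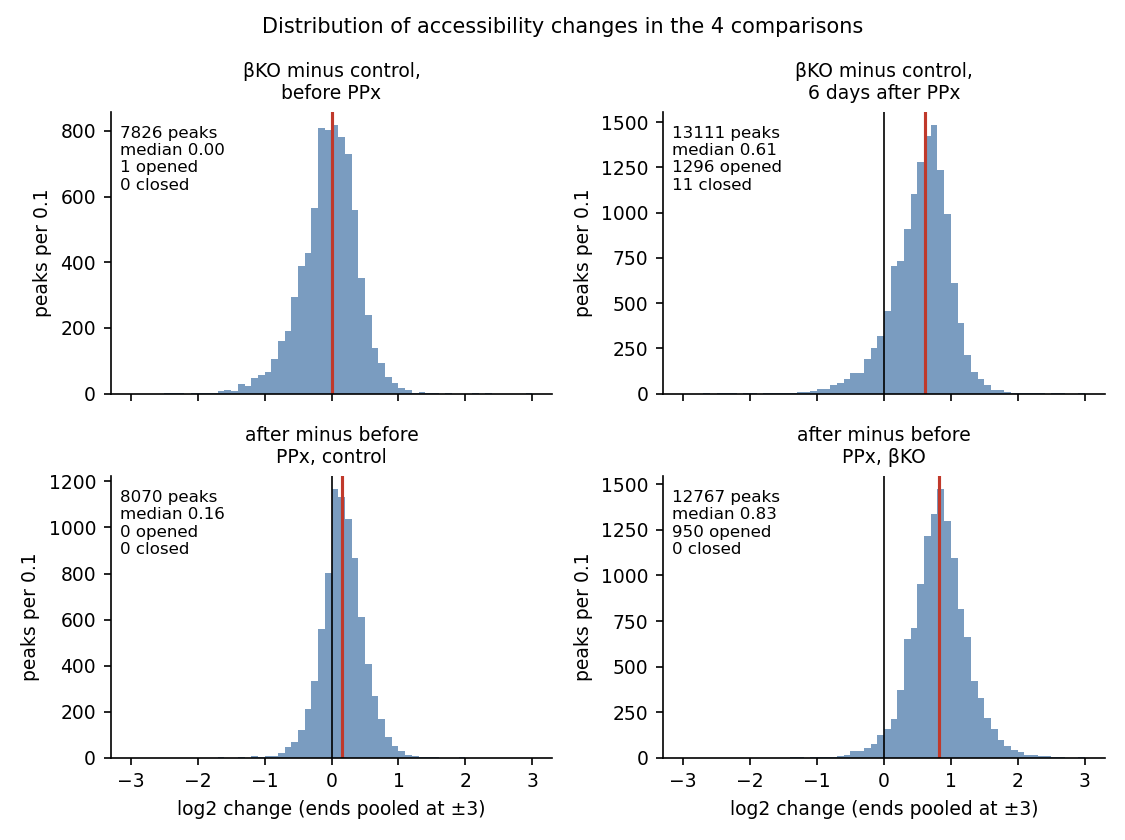
Histograms of the log2 change at all listed peaks in each of the 4 comparisons, with peaks per 0.1 on the vertical axis, 0 marked in black and the median in red. The medians are 0.00 and 0.61 for βKO against control before and after PPx, and 0.16 and 0.83 for after against before PPx in control and βKO islets.

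The Arid1a exon 9 peak read 0.40 in control and 4.04 in βKO islets after PPx in the authors' deposited table, a log2 change of 3.64 at an FDR of 0.00201. That FDR is larger than the adjustment of the other peaks gives for its rank. The peak was called in 0 of 4 control and 3 of 4 βKO libraries after PPx. The Ak5 peak at chromosome 3, 152624474 to 152625074, read 2.01 in control and 4.60 in βKO islets, at an FDR of 0.000605 in the authors' deposited table. Ak5 had another opened peak in intron 10, with a log2 change of 0.96. Of 14 genes with a pair of opened peaks, the rule took 4 in alphabetical order, Ak5 among them. The others were Acvr1c, an activin receptor gene, the aminopeptidase gene Aopep and the adaptor gene Ap1s2. The Acvr1c peaks changed by 1.05 and 1.27, those of Aopep by 1.29 and 0.99, and those of Ap1s2 by 1.18 and 0.96 on the log2 scale in the authors' deposited table.

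Among opened peaks of at least their median concentration, predicted genes left out, the 8 genes with the largest gains were read at promoters, except for a distal peak of Zfp944. The promoter peak of Pdcd2, a gene linked to ribosome assembly, read 3.97 in control and 5.48 in βKO islets in the authors' deposited table, a log2 change of 1.51 at an FDR of 0.0154. That is 0.90 above the median change. The Ins1 promoter at chromosome 19, 52263934 to 52264534, read 4.13 in control and 5.62 in βKO islets, with an FDR of 0.0154 in the authors' deposited table. It stood 0.88 above the median, and relative to that median its approximate adjusted p was 0.61. Both genotypes carry a transgene driven by an insulin promoter, whose reads cannot be separated from those of Ins1 here. Npm1, which encodes the nucleolar protein nucleophosmin, rose by 1.48, and Atp6v1a, a subunit of the vacuolar proton pump, by 1.40 on the log2 scale in the authors' deposited table. Glb1l2, the orphan nuclear receptor gene Nr6a1, and the zinc finger genes Zfp524 and Zfp944 had log2 changes of 1.39, 1.39, 1.38 and 1.37, with FDR values between 0.0212 and 0.0227 in the authors' deposited table.

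**Figure D2:**
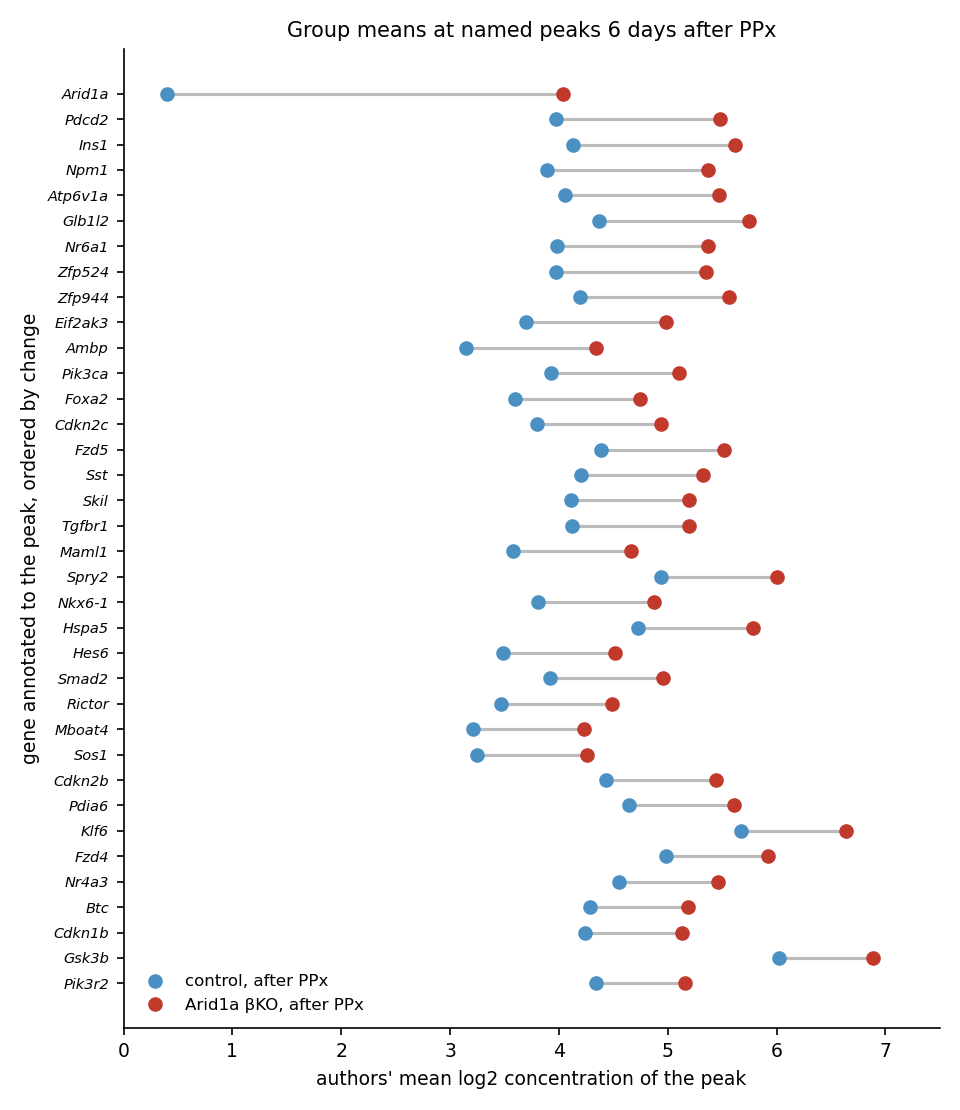
Authors' mean log2 concentration in control (blue) and βKO (red) islets after PPx at peaks named for their size of change or through a gene list, from largest change at the top to smallest at the bottom. Genes named only for a pair of opened peaks, Ak5 among them, are not drawn. Arid1a moves from 0.40 to 4.04, and the others move by between 0.82 and 1.51.

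Genes of β cell identity were among those with opened peaks. Of 19 measured genes on that list, 4 had an opened peak and 15 did not pass. Draws of matched peaks held 2.50 opened peaks on average for this list (permutation test, p = 0.232). The promoters of Foxa2 and Nkx6-1, which encode transcription factors of the β cell, rose by 1.15 and 1.05 on the log2 scale in the authors' deposited table, or 0.54 and 0.44 above the median change. The Rfx6 promoter, named after its values were seen, rose by 1.01 in the authors' deposited table. Of 7 measured genes on the α, δ and PP cell list, a peak near the somatostatin gene Sst rose by 1.12 and a peak in exon 3 of Mboat4, the ghrelin acyltransferase gene, by 1.02 in the authors' deposited table.

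Growth and stress pathways showed a few opened members each, at numbers near those of matched peaks. Of all peaks, 9.9% opened. Draws of matched peaks held on average 2.98 opened peaks for the EGF list, 3.58 for the cell cycle list and 3.39 for the unfolded protein response list. In EGF, neuregulin and ERBB signalling, 3 of 20 measured genes opened. These were Spry2, a feedback inhibitor of receptor tyrosine kinases, Sos1, a Ras exchange factor, and Btc, the EGF receptor ligand betacellulin, with log2 changes of 1.06, 1.01 and 0.90 in the authors' deposited table. Adjusted over the list alone, 2 of its 33 peaks passed. The Egfr promoter, named outside the rule and after its values were seen, read 3.96 in control and 4.37 in βKO islets, with an FDR of 0.338 in the authors' deposited table. In the cell cycle list 4 of 21 measured genes opened, among them the inhibitor genes Cdkn2c, Cdkn2b and Cdkn1b at 1.14, 1.01 and 0.89 in the authors' deposited table. The remaining one, named after its values were seen, was the cyclin gene Ccna2, at 0.98 with an FDR of 0.0493 in the authors' deposited table. In the unfolded protein response list 4 of 15 genes opened, including Eif2ak3, the PERK kinase gene, at 1.29, the chaperone gene Hspa5 at 1.05 and Pdia6 at 0.97 in the authors' deposited table.

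The TGF-β and BMP list had 4 opened genes of 14, including Skil at 1.09, Tgfbr1 at 1.08 and Smad2 at 1.03 in the authors' deposited table. In the Wnt list 3 of 13 opened, with the receptor genes Fzd5 at 1.13 and Fzd4 at 0.94 and Gsk3b at 0.87 in the authors' deposited table. In the Notch list Maml1 and Hes6 opened among 13 genes, at 1.07 and 1.03, per the authors' deposited table. Among 17 genes of insulin, IGF and PI3K signalling, Pik3ca, Rictor and Pik3r2 opened, at 1.17, 1.02 and 0.82 in the authors' deposited table. The immediate early genes Klf6 and Nr4a3 opened among 18, at 0.97 and 0.91 in the authors' deposited table. Arid1a was the only one of 13 measured SWI/SNF genes with an opened peak, and none of 8 β cell disallowed genes opened.

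Among the acinar, duct, endothelial, stromal and macrophage and leukocyte lists 1 gene was called, the duct list gene Ambp, with a log2 change of 1.20 in the authors' deposited table. No gene of any list had a closed peak, so the planned test of opened against closed peaks (Fisher's exact test, two-sided, p = 1 for each of 12 lists with a called peak) could not set the lists apart. The permutation test against matched peaks called 0 of 17 lists, the smallest adjusted p being 0.0748 for SWI/SNF genes, and without Arid1a that list gave p = 0.333 in the permutation test. The number of opened peaks per list was compared with the same draws, in a 1-sided test for an excess only. Its smallest unadjusted p was 0.192 (permutation test), for the TGF-β and BMP list with 4 opened peaks against 2.36 expected. No list thus held a clear excess of opened peaks over matched peaks, and a shortage was not tested.

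The opened peaks lay mainly at promoters. Of 1296 opened peaks, 1154 (89%) were promoter peaks, against 0 of 11 closed peaks (Fisher's exact test, two-sided, p = 4.08e-11) and 58.4% of peaks not called. Within 10 bins of peak strength the odds of a promoter were 2.78 times higher for opened peaks than for peaks not called. The median log2 change was 0.71 at promoters, 0.37 in introns and 0.39 at distal intergenic peaks. Between the genotypes before PPx, without a general gain, these medians were 0.04, -0.21 and -0.12. In βKO islets from before to after PPx they were 0.86, 0.82 and 0.74. The 11 closed peaks were annotated to 9 predicted genes, to Pkhd1, at exon 61 of 67, and to Ndufb3, at a distal peak. Pkhd1, the fibrocystin gene, read 4.79 in control and 3.63 in βKO islets, and Ndufb3, a complex I subunit gene, 3.99 and 2.80, in the authors' deposited table. Both were named after their values were seen.

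Stronger peaks gained more in this comparison. The median log2 change rose from 0.39 in the weakest of 10 bins of peaks to 0.77 in the strongest. A similar slope, from -0.12 to 0.18, was present between the genotypes before PPx without a general gain. In βKO islets from before to after PPx the ends differed little, at 0.72 and 0.78. At 10 peaks with a log2 concentration of 8 or more, 5 of them annotated to predicted genes, the median was -0.17, and all 10 lay at or below the median of the table. At an FDR under 0.01 only Ak5, Arid1a and Pttg1 passed, and adjustment over all listed peaks left 541 opened and 10 closed peaks.

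**Figure D3:**
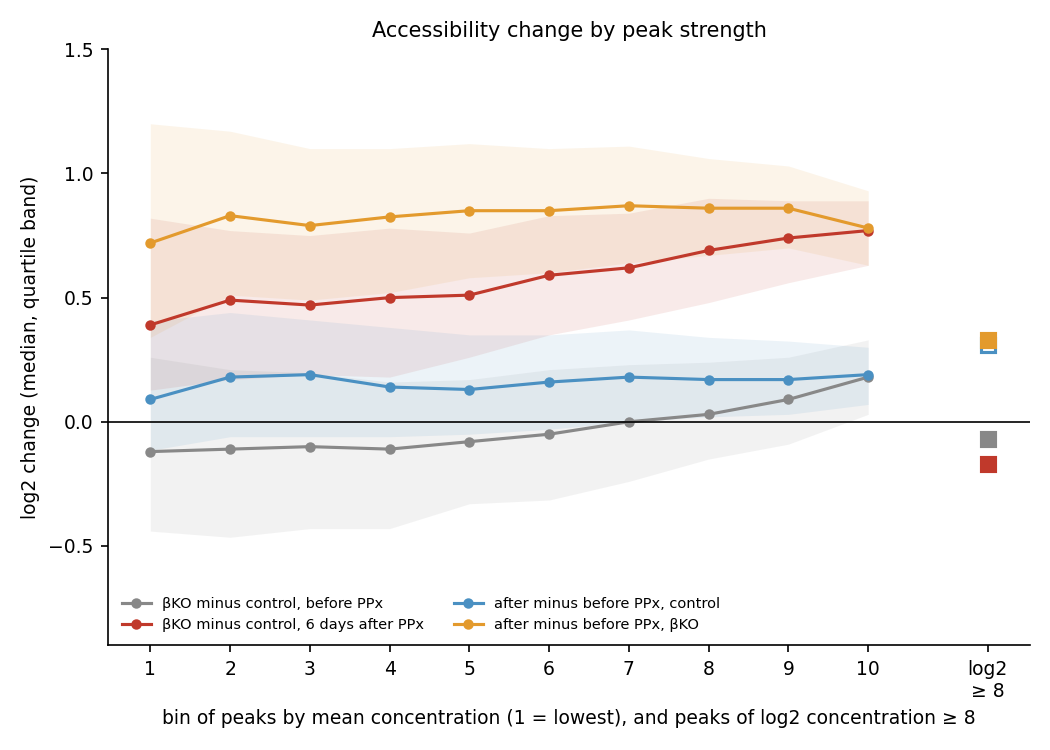
Median log2 change (lines, with quartile bands) in each of 10 equal bins of peaks ranked by mean log2 concentration, and at peaks with a log2 concentration of 8 or more (squares; peaks without a usable p-value left out). βKO against control after PPx goes from 0.39 to 0.77 across bins and lies at -0.17 at the square.

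In control islets, no single peak passed the threshold after PPx. In the authors' deposited table, 0 of 8070 peaks passed an FDR of 0.05, the smallest FDR was 0.619, and 72.8% of peaks had a higher value after PPx. This does not show that accessibility was unchanged. At an unadjusted p under 0.05 it listed 196 higher and 8 lower peaks, where 404 would be expected by chance. The median log2 change was 0.16, with quartiles of -0.02 and 0.36. The smallest adjusted p of the gene lists was 0.927 in the permutation test. Among genes chosen after their values were seen, the promoter of Pttg1, the securin gene, read 3.75 before and 2.25 after PPx, at an FDR of 0.999 in the authors' deposited table. The Arid1a exon 9 region was not listed in this comparison.

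In βKO islets, accessibility was higher after PPx than before at 950 peaks and lower at none. In the authors' deposited table, 97.1% of 12767 peaks had a higher value after PPx, and the median log2 change was 0.83, a 1.78-fold difference. At an unadjusted p under 0.05 it listed 5027 higher and 3 lower peaks. Relative to the median, 0 peaks were higher and 0 lower at an adjusted p under 0.05 in the approximate test. Adjustment over all listed peaks left 573 opened peaks.

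Among opened peaks of at least their median concentration, again without predicted genes, the promoters of Mrps14, Spc25 and Creg1 gained most, each with a log2 change of 1.80 in the authors' deposited table. Weaker peaks included larger gains. Mrps14, a mitochondrial ribosomal protein gene, read 3.65 before and 5.46 after PPx at chromosome 1, 160194841 to 160195441, with an FDR of 0.0077 in the authors' deposited table. Spc25, a kinetochore gene, read 3.32 before and 5.12 after, with an FDR of 0.0192 in the authors' deposited table. The promoters of Lyrm2, Dctn6, a dynactin subunit gene, and Zfp949 rose by 1.68, 1.67 and 1.66 on the log2 scale in the authors' deposited table. A peak in intron 2 of Poc1b, a centriole gene, rose by 1.71 and a distal peak of Gch1, which makes the first enzyme of tetrahydrobiopterin synthesis, by 1.63 in the authors' deposited table. A pair of opened peaks was annotated to each of 18 genes, of which the rule took 4 in alphabetical order. These were Abhd4, Arfip1, the antiproliferative gene Btg2 and Creb1, the cAMP-responsive factor gene. Their larger changes were 1.52, 2.20, 1.25 and 1.93 on the log2 scale in the authors' deposited table. At the Arfip1 peak of larger change, the overlapping peak after PPx read 3.66 in control and 4.30 in βKO islets, at an FDR of 0.177.

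The Arid1a exon 9 peak went the other way, from 5.26 before to 4.04 after PPx in βKO islets, at a p of 0.00918 and an FDR of 0.0584 in the authors' deposited table, so it did not pass the threshold. Within the EGF, neuregulin and ERBB list, Adam17, which sheds EGF receptor ligands, and Spry2 opened among 20 measured genes, at 1.17 and 1.01 in the authors' deposited table. In β cell identity 1 of 18 genes opened, Slc30a8 at 1.56 in the authors' deposited table. Its intron 2 peak rose from 2.88 to 4.43 in βKO islets. The overlapping peak after PPx read 4.49 in control and 4.34 in βKO islets at an FDR of 0.74, so the rise only reached the control level. Opened members of other lists were Skp2, a cell cycle ubiquitin ligase gene, at 1.08, the SWI/SNF gene Arid1b at 1.72, Bmpr2 at 1.77 and Id2 at 1.12 in the authors' deposited table. The overlapping Arid1b peak after PPx read 3.55 in control and 4.18 in βKO islets, at an FDR of 0.185. Also opened were Gsk3b at 0.94, Numbl at 1.42, Pdpk1 at 1.30 and Akt2 at 1.48 in the authors' deposited table. Of 15 unfolded protein response genes, Eif2ak3 at 1.52, Hspa5 at 1.08 and Edem1 at 1.07 opened in the authors' deposited table. This list held 4 opened peaks against 1.97 expected from matched draws (permutation test, p = 0.127), the smallest such p of any list in this comparison.

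A distal peak of the macrophage marker Csf1r rose by 2.01 in βKO islets after PPx in the authors' deposited table, the 1 opened gene of 5 measured on that list. It went from 2.02 to 4.03 and was called in 0 of 3 libraries before and 2 of 4 after PPx. The overlapping peak after PPx read 3.58 in control and 3.99 in βKO islets at an FDR of 0.372, so the genotypes did not differ there past the threshold. No gene of the α, δ and PP, disallowed, immediate early, acinar, duct, endothelial or stromal lists opened. TGF-β and BMP genes stood 0.29 below matched peaks (mean excess -0.29; permutation test, p = 0.0018, adjusted 0.0306 over the lists of this comparison). Adjusted over the lists of all 4 comparisons, this too was 0.0594. This comparison and that of the genotypes before PPx share the βKO libraries taken before PPx, so the opposite signs of this list in them are not independent. Promoters made up 82.2% of opened peaks and 61.4% of the rest, and with no closed peak the planned test of opened against closed was not possible.

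The βKO effect was compared between times over 7504 peaks listed in both genotype comparisons. The median effect was 0.00 before and 0.66 after PPx at these peaks, and the median difference was 0.64. No peak passed the approximate interaction test, the smallest adjusted p being 0.0935, while 1075 peaks were higher and 9 lower at an unadjusted p under 0.05. Among the 2 peaks with an FDR under 0.01 in at least 1 table, Pttg1 passed, with an effect of -0.24 before and 2.18 after PPx (approximate adjusted p of 0.000366), and Arid1a did not. Selection by the size of the effect after PPx favours such a call. The PPx response likewise had a median of 0.16 in control and 0.83 in βKO islets over 7536 shared peaks, with no peak past the interaction test over all of them (smallest adjusted p 0.161). It compares the same 4 groups as the contrast above, through the other deposited tables. Limited to 3 peaks with an FDR under 0.01, all 3 passed. The promoters of Nedd8, Morn2 and Mrps14 differed in response by 2.63, 2.09 and 1.81 on the log2 scale, each with an approximate adjusted p of 0.000444 or less. They too were selected by the size of their response in βKO islets.

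The Arid1a exon 9 peak was the 1 peak opened by genotype at both times, where 0.156 would be expected for independent lists. Across the 7504 shared peaks the 2 genotype effects, which rest on different mice, correlated with a Pearson's r of 0.29 and a Spearman's rho of 0.27. Peaks are not independent replicates, and no p is given. The PPx responses in control and βKO islets, also from different mice, had an r of 0.01 over shared peaks. Of the peaks opened by genotype after PPx and by PPx in βKO islets, 321 were the same, where 100 would be expected for independent lists. Those comparisons share the βKO libraries taken after PPx. Their changes correlated with an r of 0.36 against 0.46 in simulated unchanged groups, with a covariance of 0.060 against 0.098, so part or all of the excess over independent lists may come from the shared libraries. Simulated groups without any change gave 0 shared calls. With a gain alike at all peaks and the numbers of opened peaks held, a simulation chosen after the result was seen gave a mean of 345 shared peaks (312 to 382 over 100 draws) when the libraries were shared and of 122 (97 to 150) when they were drawn apart.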

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

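All tests of explanations in this part, and the limited test of the PPx response, were chosen after the results were seen. The Pttg1 promoter drew attention because the βKO effect differed between the times, by 2.42 on the log2 scale, in the planned interaction test limited to 2 peaks with an FDR under 0.01. Over all 7504 shared peaks its adjusted p was 0.15. The promoters of Nedd8, Morn2 and Mrps14 drew attention in the same way, as the PPx response differed between the genotypes by 2.63, 2.09 and 1.81 in the test limited to 3 peaks with an FDR under 0.01. Over all 7536 shared peaks their adjusted p was at least 0.161.

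The first pattern is the nearly one-directional gain in βKO islets after PPx, 1296 peaks opened against 11 closed. A single scaling factor for whole libraries as the whole cause is argued against by 10 peaks of very high concentration, though 5 of them were annotated to predicted genes. Their median change lay at -0.78 relative to the median of the table, with all 10 at or below it. From before to after PPx, the median change of such peaks was 0.33 in βKO and 0.31 in control islets. A scaling factor as part of the cause is not excluded by these peaks. Entry of peaks into the table through calls in the βKO libraries after PPx is argued against too, because the median change was 0.66 over peaks also listed before PPx, which were chosen without those libraries. A larger share of reads in peaks in these libraries and a general opening of chromatin cannot be told apart, since values per library and a spike-in were not used here. The slope across peak strength does not decide it. The strongest of 10 bins gained 0.38 more than the weakest in this comparison, but 0.30 more before PPx without a general gain, and only 0.06 more in βKO islets from before to after PPx. The loss of Arid1a, not verified here, during the response to PPx stays open as a biological explanation. Every βKO mouse carried TRE-Cre and no control mouse did, so an effect of Cre itself cannot be told apart from that loss.

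The second pattern is the gain at Arid1a exon 9. A general gain of βKO libraries is argued against, since the peak stood 4.28 above the median change before PPx, when that median was 0.00. A candidate explanation is DNA of a recombined or excised Arid1a allele, as floxed alleles are built to lose a part of the gene when Cre is made. The peak's level was lower after than before PPx in βKO islets, a change of -1.22 with an FDR of 0.0584. It was called in 3 of 3 βKO libraries before PPx and in 3 of 4 after. The fall may come from a library without the call or from dilution in dividing cells, and it does not test this explanation. With 1 listed peak in the gene and the floxed part not stated in the labels, such DNA cannot be told apart from a change in accessibility.

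The third pattern is the correlation of the genotype effects before and after PPx. Peak strength and promoter class are argued against as the whole cause, since r was 0.23 within strata of both. Base composition cannot be told apart from a genotype effect already present before PPx, as the r of 0.29 could not be recomputed within classes of GC content without a genome sequence.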

How the results depend on the processing

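Adjustment over all listed peaks, centring on the median, counting of repeated rows, the permutation test, the distance to the gene span, the omission of Arid1a, the interaction taken through the PPx effects and the treatment of unusable p-values were chosen after seeing the data. Of 70 alternative values, 55 kept their direction and their side of the threshold or stayed within 1.5 times the count. However, 23 of them were bound to give 0 again, such as a stricter rule applied to no called peak, and 32 of the other 47 stayed the same. Opened peaks after PPx in βKO against control numbered 1296 and fell to 3 at an FDR under 0.01, 840 at a log2 change of 1 or more, 541 with adjustment over all listed peaks and 2 after centring. Closed peaks there numbered 11 and became 0 at an FDR under 0.01, 7 at or above the median concentration, 17 with repeated rows and 49 after centring. Opened peaks in βKO after against before PPx numbered 950 and fell to 5 at an FDR under 0.01, 573 with adjustment over all listed peaks and 0 after centring. Fewer peaks pass a stricter threshold by construction, and adjustment over more peaks raises each adjusted p. Centring takes away the shift shared by most peaks, so these counts rest on treating that shift as change. The interaction, taken as the genotype effect after minus before PPx, gave 0 calls, 1 (Pttg1) among peaks with an FDR under 0.01, and 2 (Pgk1 and Psmd1) when peaks with an unusable p-value took the error of like peaks. Taken as the PPx effect in βKO minus control, it gave 0 calls over all shared peaks and 3 of 3 (Nedd8, Morn2 and Mrps14) among peaks with an FDR under 0.01, a set selected for a large effect in βKO islets. The excess of SWI/SNF genes before PPx fell from 0.50 to 0.00375 without Arid1a, which carried it. Of 66 list tests by permutation, 0 passed when adjusted over the lists of all 4 comparisons, a choice added after seeing the data, so the TGF-β and BMP calls within single comparisons depend on that choice. The counts of the comparison before PPx and of the control comparison were the same under all alternatives run, though many of these could not have changed a count of 0. Not run were leaving out libraries, other splits of the libraries, motif searches and the distance to the transcription start. At an FDR under 0.01 no peak closed, so neither the promoter test nor the list test could be made. No paired analysis was possible because the groups share no replicate numbers. The depth of each library is unknown, and a median log2 concentration near 3.8 after PPx leaves small changes at single peaks undetectable.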

Other observations

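The gene families and peaks in this part were chosen after the data were seen. Promoters and other peaks of mitochondrial ribosomal protein genes gained more than matched peaks in βKO islets from before to after PPx. The mean excess was 0.24 on the log2 scale over 42 peaks at 33 genes, and 7 of the genes had an opened peak, among them Mrps14, Mrps36, Mrps31 and Mrpl46 at 1.80, 1.56, 1.46 and 1.43 in the authors' deposited table. The permutation p was 0.0002, the smallest that 10000 draws can give, and 0.0072 when adjusted over 9 families and 4 comparisons. The family was picked after Mrps14 was seen among the smallest p-values of this comparison, so this p does not test it, and a response of the family cannot be told apart from a random set of peaks of like strength and promoter class. The mean excess was 0.08 between the genotypes after PPx (permutation test, p = 0.0876), -0.06 before PPx (permutation test, p = 0.508) and 0.02 in control islets from before to after PPx (permutation test, p = 0.788).

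Within the genotype comparison after PPx, zinc finger genes stood 0.05 above matched peaks over 269 peaks, and potassium and calcium channel genes 0.18 below (mean excess -0.18) over 64 peaks, each with an adjusted p of 0.0342 over the families of that comparison in the permutation test. Adjusted over all families and comparisons these were 0.0912 and 0.0864, neither of them under 0.05. Cytosolic ribosomal protein, complex I, proteasome, kinetochore, solute carrier and adhesion genes gave no adjusted p under 0.05 there.

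The Pttg1 promoter read 2.20 in control and 4.38 in βKO islets after PPx, at an FDR of 0.00701, and 3.75 before and 2.25 after PPx in control islets, in the authors' deposited table. In βKO islets it read 3.47 before and 4.38 after PPx, a change of 0.91 at an FDR of 0.111, where the median change was 0.83. The Rfxap promoter was higher by 1.60 in βKO than in control islets after PPx, at an FDR of 0.0118 in the authors' deposited table. Much of this gap lay in control islets, where it read 4.38 before and 3.35 after PPx, at an FDR of 0.999. In βKO islets it read 4.24 before and 4.89 after PPx, a change of 0.65 at an FDR of 0.128. The Pgk1 promoter on chromosome X read 4.84 before and 8.81 after PPx in control islets and 6.68 in βKO islets after PPx, with a p-value of 1 for the control comparison in the authors' deposited table, so its change there has no usable test. In βKO islets the promoter read 4.84 before and 6.67 after PPx, at a p of 0.00479 and an FDR of 0.0503 in the authors' deposited table. Before PPx, promoters made up 70.0% of all peaks listed between the genotypes. They made up 63.6% of 66 peaks higher and 30% of 180 peaks lower in βKO islets at an unadjusted p under 0.05 (Fisher's exact test, two-sided, p = 3.31e-06). The lower peaks were thus poor in promoters, while the higher ones were not rich in them. The total of such peaks was below that expected by chance. Fisher's test treats peaks as independent and does not account for peak strength. Promoter peaks had a median log2 concentration of 4.18 against 3.73 at distal peaks. The change before PPx rose with strength, from -0.12 in the weakest bin to 0.18 in the strongest.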
